A study of Mus musculus with 6 samples.

How the data were processed

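The study measured messenger RNA in single immune cells from the spleen and bone marrow (BM) of C57BL/KaLwRij mice, either naive or carrying 5T33MM, a transplantable mouse multiple myeloma, at 14 or 20 days after inoculation (DPI in the labels). Per the labels, sorted 7-AAD− CD45+ 3H2−/CS1− cells were run with 3' chemistry version 3.1 of 10x Genomics. As background, 3H2 is an antibody to the idiotype of the 5T33 immunoglobulin and CS1 is the surface protein encoded by Slamf7, so the gate removed live leukocytes that carried either mark. Each of the 6 groups, made of 2 tissues and 3 stages, held 1 library, and the labels do not state how many animals went into a library.

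Per the submitters' processing notes, Cell Ranger was run against mm10, with no version stated. The deposited matrices held raw UMI counts per gene and barcode with no barcode filtering. Matrices were read for 4 libraries: naive spleen, spleen at 14 days, spleen at 20 days and naive BM. Gene expression in BM at 14 and 20 days was not analysed here. The deposited metadata table listed 47129 cells kept by the authors, with 22 detailed and 15 broad cell type names, subtype names, the percent of UMIs on mitochondrial genes and a doublet score. The tools behind this table, its cell type names and its doublet score were not stated. The mitochondrial percent given by the authors was recomputed from the 4 matrices and equalled the deposited value in every cell within 1e-06, and its maximum was 19.9%. The deposited doublet score was used only to leave cells out in an alternative.

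Groups followed the labels, and cells took the authors' cell type. The share of a cell type was its cells over all cells of the library, with an exact Clopper-Pearson 95% interval, and 2 shares were compared by their ratio with an exact conditional binomial interval. Counts were summed over the cells of a type in a library and scaled to CPM by the summed UMIs of that type, and the log2 ratio of CPM plus 5 gave the size of a difference. The fold was the ratio of CPM with an exact conditional binomial 95% interval. A count of 0 was replaced by its floor of 3 counts, and such a fold was written as a bound. This bound rests on the floor alone, and the counting interval can start below it. With 1 library per group there were no replicates, no test between groups was possible, and every interval covers counting error only. Intervals of expression folds treat each UMI as an independent draw and leave out differences between cells of a type. A cell type needed 100 cells in both libraries, and neutrophils, non-classical monocytes (Monocytes NC) and NKT cells, with 50 cells or more, were added after the data were examined. Coordinates came from GENCODE vM21 on GRCm38. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19 and matplotlib 3.10.9.

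There were 16 fixed gene lists: type I interferon response, interferon gamma induced, MHC class I, MHC class II, cytotoxic effector, checkpoint receptors, naive T cell, regulatory T cell, proliferation, immature neutrophil granule, mature neutrophil, myeloid suppressor associated, immediate early and stress, NK maturation, immunoglobulin constant and myeloma growth factors. Erythroid, platelet and plasma cell markers served as signs of other cells. A list was summarised by the median log2 ratio of members with 10 UMIs or more over both libraries, by the members at least 1.5-fold higher or lower, and by the percentile of its median among 10000 random lists matched on expression. Named genes followed a fixed rule: 50 UMIs in the higher library, seen in 5% of its cells of the type, a log2 ratio of at least 1, an interval beyond 1.5-fold, and a level of at least 0.5 times that in empty droplets. Immunoglobulin, haemoglobin, ribosomal protein, mitochondrial and sex-linked genes and unnamed gene models were set aside. Up to 4 genes per direction were named in each type. List members were named by their summed UMIs. The lists, the rule for named genes, the comparisons, the summaries and the first set of alternatives were chosen before the data were examined. Any other gene or use of a list in the text was chosen after its values were seen.

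Free RNA was read from barcodes with 1 to 50 UMIs outside the metadata table, as CPM of their sum. Scrublet, run through scanpy, called 7 of 3526 cells (0.199%) in naive BM, 13 of 5630 (0.231%) in naive spleen, 3 of 5677 (0.0528%) in spleen at 14 days and 47 of 5704 (0.824%) in spleen at 20 days. Its automatic threshold called almost no cells in naive BM, naive spleen and spleen at 14 days and did not work there, so the values without its calls are no evidence on doublets. The authors' score was above 0.5 in 32.9% of naive BM cells and in 11.6%, 9.95% and 8.70% of spleen cells of the naive, 14-day and 20-day libraries. No cell was removed for the values in the report.

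The count, size and interval parts of the rule were tested on simulated data, by changing 200 genes in counts drawn from 1 profile at the depths of spleen at 20 days and naive spleen. In B cells it named 42 of 53 genes set to 0.25-fold, 5 of 48 at 0.5-fold, 39 of 47 at 2.5-fold and 52 of 52 at 4-fold, out of 11428 genes, and no unchanged gene. In NK cells it named 53 of 53, 36 of 54, 41 of 47 and 46 of 46 of 8618 genes, and no unchanged gene. Intervals covered the true fold for 95.7% of genes in B cells and 96.2% in NK cells. The changed list stood at percentile 100 in both, and 39 of 40 and 38 of 40 unchanged lists lay between percentiles 2.5 and 97.5. The draws were Poisson counts, the model on which the intervals rest, so this coverage was largely set in advance. They hold no difference between cells of a type or between animals.

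Total UMIs were 50352058 in naive spleen, 76392769 in spleen at 14 days, 54825960 in spleen at 20 days and 47616389 in naive BM. Alternatives planned at the start were cells with 1000 UMIs or more, B cells out of the denominator, Scrublet calls left out, scaling by the median ratio of genes, pseudocounts of 1 and 20 CPM, 5% of empty-droplet RNA subtracted, immunoglobulin and haemoglobin genes out of the total, cells thinned to 1000 UMIs, list members with 1 UMI, and empty droplets of 1 to 10 or 10 to 100 UMIs. Alternatives added after seeing the data were broad cell type names, a doublet score above 0.5 left out, the 5% highest Scrublet scores left out, naive-like T cells alone, B class cells with at least 20 UMIs of Jchain left out, and the proliferating T cell subtype left out of CD8+ T cells.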

Results

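Messenger RNA was measured in single live leukocytes of the spleen and bone marrow (BM) of C57BL/KaLwRij mice that were naive or bore the 5T33MM myeloma, at 14 and 20 days after tumour inoculation. Sorted 7-AAD− CD45+ 3H2−/CS1− cells gave 1 library for each tissue and stage, 6 in all. The authors kept 5630 cells of naive spleen, 5677 of spleen at 14 days, 5704 of spleen at 20 days, 3526 of naive BM, 14735 of BM at 14 days and 11857 of BM at 20 days. Spleen libraries held 50352058 UMIs when naive, 76392769 at 14 days and 54825960 at 20 days, and naive BM held 47616389. Kept cells had a median of 5594.5, 7074, 5391 and 7014.5 UMIs in these 4 libraries, and held 73.7%, 81.7%, 76.1% and 82.0% of all UMIs. There were no replicates, so each interval given is a 95% interval that covers counting error only and no difference between animals. Intervals of expression folds also leave out differences between cells of a type.

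The first question was how immune cell types in the spleen differed between stages of myeloma. CD8+ T cells made up 15.2% of sorted cells in naive spleen, 17.6% at 14 days and 24.3% at 20 days, a share 1.60-fold that of naive spleen at 20 days (interval 1.47 to 1.74). CD4+ T cells, which help other immune cells, went from 23.2% to 16.4% at 14 days (0.705-fold, 0.648 to 0.768) and stood at 19.9% at 20 days (0.856-fold, 0.790 to 0.928). All spleen cells of the authors' proliferating T cell subtype lay in the CD8+ class. They were 58 of 856 CD8+ cells in naive spleen, 307 of 998 at 14 days and 289 of 1388 at 20 days. Both T cell shares thus depend on that placement, and the direction of the CD8+ share at 14 days may rest on it. Neutrophils were 0.888% of naive spleen, 3.73% at 14 days (4.20-fold, 3.08 to 5.84) and 1.91% at 20 days (2.15-fold, 1.53 to 3.07). B cells made up 44.3% and 44.1% at the first stages and 38.3% at 20 days (0.864-fold, 0.816 to 0.916). Macrophages, which clear old red cells in the spleen, were 43 cells in naive spleen, 4 at 14 days (0.0923-fold, 0.0241 to 0.254) and 14 at 20 days (0.321-fold, 0.162 to 0.599).

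Smaller spleen types moved too. NKT cells, T cells that see lipid antigens, had 1.23%, 1.14% and 2.40% of cells, 1.96-fold naive at 20 days (1.46 to 2.66), and 1.23-fold when the authors' broad cell names were used. Granulocyte progenitors (GMP/GP) were 6 cells in naive spleen, 24 at 14 days (3.97-fold, 1.58 to 11.9) and 28 at 20 days (4.61-fold, 1.87 to 13.6). The class named non-classical monocytes was 1.33-fold at 14 days (0.997 to 1.79) and 0.599-fold at 20 days (0.415 to 0.859). By the authors' subtypes, however, 39 of its 84 naive cells were non-classical against 0 of 113 at 14 days and 0 of 51 at 20 days, when 111 and 50 were interferon-marked, so its fold is no measure of non-classical cells. Among dendritic cells, the cross-presenting cDC1 were 1.32-fold at 14 days (0.587 to 3.06) and 0.165-fold at 20 days (0.0179 to 0.739, 2 cells against 12), cDC2 1.16-fold (0.771 to 1.76) and 0.408-fold (0.226 to 0.710), and interferon-producing pDC 1.86-fold (1.12 to 3.16) and 0.671-fold (0.340 to 1.29). The broad cDC name gave 1.39-fold (1.04 to 1.87) and 0.554-fold (0.377 to 0.804). NK cells, some of which carry the CS1 protein that the gate removed, held 4.01%, 3.75% and 3.54%, with intervals of the fold that included 1 (0.771 to 1.13 and 0.726 to 1.07), while at 20 days the authors' broad name gave 0.807-fold (0.661 to 0.985) and leaving out the 5% highest Scrublet scores gave 1.11-fold, on the other side of 1. Between 14 and 20 days CD8+ T cells were 1.38-fold (1.275 to 1.503), neutrophils 0.512-fold (0.402 to 0.648) and NKT cells 2.10-fold (1.55 to 2.86). The macrophages had median depths of 3525, 1027.5 and 522.5 UMIs, and among cells with at least 1000 UMIs their fold at 20 days was 0.118.

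**Figure D1:**
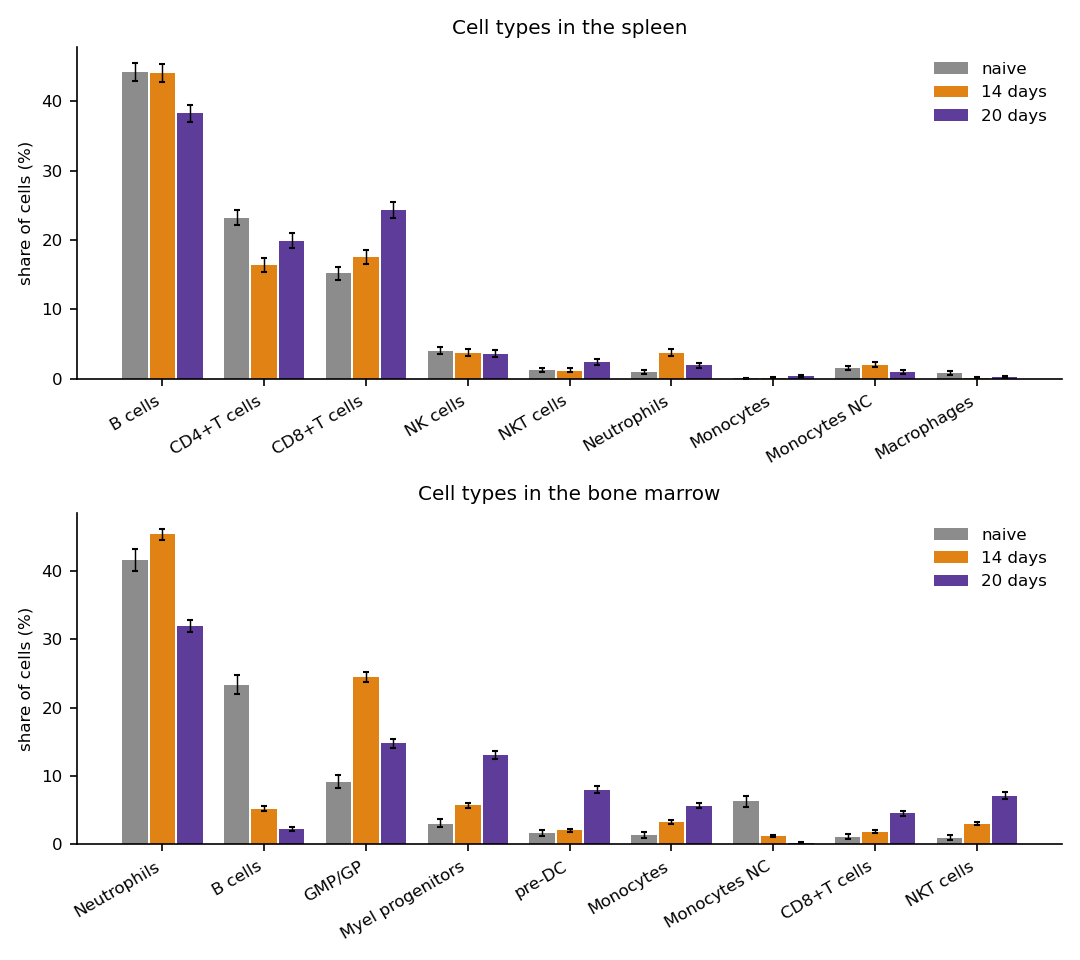
Bars show the share of cells (percent of the library) of each cell type in naive, 14-day and 20-day spleen and BM, and error bars are exact Clopper-Pearson 95% intervals for counting error. Spleen CD8+ T cells stand at 15.2%, 17.6% and 24.3%, and BM B cells at 23.3%, 5.19% and 2.18%. The CD8+ class holds all cells of the authors' proliferating T cell subtype.

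In BM, where this myeloma grows, B cells and the class named non-classical monocytes had lower shares at both days than in naive BM. B cells were 23.3% of sorted 7-AAD− CD45+ 3H2−/CS1− cells in naive BM, 5.19% at 14 days (0.222-fold, 0.201 to 0.246) and 2.18% at 20 days (0.0936-fold, 0.0811 to 0.108). The class named non-classical monocytes went from 6.27% to 1.19% (0.191-fold, 0.155 to 0.233) and 0.219% (0.0350-fold, 0.0224 to 0.0527). By the authors' subtypes the 221 naive cells of this class were 143 classical, 36 interferon-marked and 42 non-classical monocytes, and the 176 at 14 days 6, 153 and 17. Its fold is thus no measure of non-classical cells. The non-classical subtype was 0.0969-fold at 14 days (0.0517 to 0.174) and had 0 cells at 20 days. GMP/GP, a class that holds progenitors of granulocytes, went from 9.19% to 24.5% (2.66-fold, 2.38 to 2.99) and 14.8% (1.61-fold, 1.43 to 1.82). Over all libraries 3750 GMP/GP cells had the broad name Neu precursors and 1990 the broad name Precursors. In BM Neu precursors were 2.98-fold at 14 days (2.60 to 3.44) and 0.978-fold at 20 days (0.840 to 1.14). Precursors were 3.62-fold at 20 days (3.06 to 4.33), so the rise at 20 days depended on the name used. CD8+ T cells had 1.08%, 1.80% (1.67-fold, 1.18 to 2.41) and 4.55% (4.22-fold, 3.03 to 6.03). By the broad name their fold at 14 days was 1.43 (0.995 to 2.11), an interval that included no change. The detailed CD8+ class held all BM cells of the proliferating T cell subtype, 9 of 38, 107 of 265 and 117 of 539. NKT cells had 0.936%, 3.03% (3.24-fold, 2.27 to 4.77) and 7.11% (7.60-fold, 5.37 to 11.1). Among the authors' lymphoid subtypes in BM, NKT BM had 20, 259 and 576 cells and NKT 3, 0 and 23. In spleen NKT BM had 2, 0 and 2 cells, so the NKT folds of the tissues may rest on different subtypes.

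Myeloid progenitors in BM were 3.03%, 5.72% and 13.1% of cells, 4.32-fold naive at 20 days (3.55 to 5.30). Pre-DC, the precursors of dendritic cells, were 1.26-fold at 14 days (0.946 to 1.70) and 4.96-fold at 20 days (3.80 to 6.60). The class named HSC, for blood stem cells, was 0.718-fold at 14 days (0.437 to 1.22) and 2.78-fold at 20 days (1.79 to 4.54). The authors' subtype HSC/CMP had the same BM counts, 22, 66 and 206 cells. By that name the class also holds common myeloid progenitors (CMP), so its fold is no measure of stem cells alone. Monocytes by the detailed name were 2.49-fold at 14 days (1.84 to 3.43) and 4.25-fold at 20 days (3.16 to 5.84), while the broad name, which also holds non-classical monocytes and most myeloid progenitors, gave 0.918-fold (0.818 to 1.03) and 1.60-fold (1.43 to 1.795). The authors' monocyte subtypes together were 0.591-fold at 14 days (0.512 to 0.684) and 0.768-fold at 20 days (0.666 to 0.887), and classical monocytes among them 0.276-fold (0.224 to 0.339) and 1.07-fold (0.903 to 1.27), so the direction depended on the names used. Neutrophils made up 41.6%, 45.4% and 31.9%, or 1.09-fold at 14 days (1.03 to 1.16) and 0.768-fold at 20 days (0.723 to 0.816). With B cells out of the denominator the neutrophil fold at 14 days was 0.882, a turned direction. Lymphoid progenitors were 0.284-fold at 14 days (0.230 to 0.351) and 0.691-fold at 20 days (0.575 to 0.835). The broad names put 159 of 166 naive cells, 159 of 197 at 14 days and 169 of 386 at 20 days among B cells. The broad name Precursors held 6, 37 and 202 of these cells, so the class differed in makeup between libraries and its fold joins unlike cells. The authors' doublet score was above 0.5 in 32.9% of naive BM cells, and without such cells the folds at 14 and 20 days were 2.98 and 6.60 for myeloid progenitors.

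Over all 856, 998 and 1388 CD8+ T cells of the spleen, the authors' naive-like subtype had 89.6%, 36.7% and 28.9%, effector memory cells, which have met antigen, 1.87%, 14.7% and 39.3%, proliferating T cells 6.78%, 30.8% and 20.8%, and 1.52%, 10.2% and 6.56% had no subtype. Among only the cells named naive-like, interferon or effector memory (785, 589 and 1008), the naive-like subtype went from 97.7% to 62.1% at 14 days and 39.8% at 20 days, and effector memory from 2.04% to 24.96% (12.2-fold, 7.29 to 21.99) and 54.1% (26.5-fold, 16.2 to 46.7). Interferon-marked cells were 0.255%, 12.9% and 6.15% of these 3 subtypes. Over all 38, 265 and 539 CD8+ T cells of BM, the interferon subtype had 2.63%, 17.7% and 7.98%, effector memory 2.63%, 4.91% and 29.3%, proliferating T cells 23.7%, 40.4% and 21.7%, and 2.63%, 34.3% and 37.8% had no subtype. Among the 1266, 895 and 1067 spleen cells of the 3 CD4+ subtypes without Tregs, interferon-marked cells were 2.76%, 33.6% (12.2-fold, 8.55 to 17.8) and 28.0% (10.1-fold, 7.13 to 14.8), while naive-like CD4+ T cells were 77.1%, 20.7% and 22.9%. The interferon subtype was 11.8%, 95.8% and 91.7% of the monocyte subtypes in spleen, and 18.3%, 66.6% and 8.09% in BM. Subtype names rest on expression, so these shares and the gene values of the same cells are not independent.

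**Figure D2:**
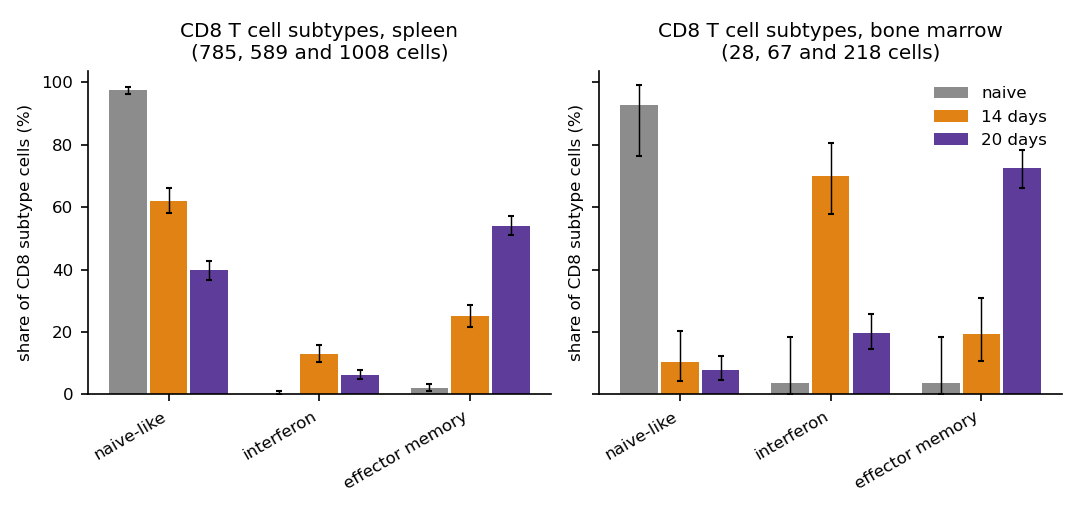
Bars show naive-like, interferon and effector memory cells as a percent of these 3 CD8+ subtypes together in spleen (785, 589 and 1008 cells) and BM (28, 67 and 218 cells), leaving out proliferating T cells and cells with no subtype, with exact 95% intervals. Effector memory cells go from 2.04% to 54.1% in spleen and from 3.57% to 72.5% in BM.

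Spleen cells at 14 days were compared with naive spleen to ask how each type's expression differed early in myeloma. Genes switched on by type I interferon, the antiviral cytokine, were higher in all of B cells, CD4+ T cells, CD8+ T cells and NK cells, in 17 of 17 measured list members in each. The median log2 ratio was 2.13 in B cells, 2.28 in CD4+ T cells, 1.95 in CD8+ T cells and 2.01 in NK cells, each at percentile 100 of matched random lists. Isg15, a ubiquitin-like antiviral protein (ENSMUSG00000035692, chr4:156199424-156200818 on GRCm38), was 5.95-fold in B cells (5.47 to 6.49), 8.82-fold in CD4+ T cells, 8.19-fold in CD8+ T cells and 5.36-fold in NK cells. Ifi27l2a, another interferon-induced gene, was 3.76-fold, 6.03-fold, 8.34-fold and 10.5-fold in the same order. In empty droplets, which show free RNA, Isg15 was 2.89-fold.

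Interferon gamma induced genes had medians of 1.47 in B cells, with 13 of 15 members higher, 1.33 in CD4+ T cells, 1.01 in CD8+ T cells and 0.75 in NK cells. Psmb9, an immunoproteasome subunit, was 2.45-fold and Irgm1, a GTPase of cell defence, 3.26-fold in B cells. MHC class I genes, which show peptides to CD8+ T cells, had medians of 0.64 in B cells, 0.72 in CD4+ T cells, 0.41 in CD8+ T cells and 0.25 in NK cells. The class I gene H2-Q7 was 2.66-fold and B2m, the shared light chain, 1.37-fold in B cells. MHC class II genes in B cells had a median of −0.27 (percentile 4.03), with the invariant chain Cd74 at 0.66-fold.

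B cells at 14 days showed more proliferation transcripts and less of their complement and IgE receptors. Iigp1, a GTPase against intracellular parasites (ENSMUSG00000054072, chr18:60376027-60392634), was 149-fold (86.8 to 279.6) from 13 naive UMIs. Slpi, a protease inhibitor, was 25.6-fold, Pclaf, a partner of PCNA in DNA synthesis, 33.1-fold and Ly6c2, a surface antigen, 20.5-fold, with Ly6c2 at 812 CPM in B cells against 1484 in empty droplets. Fcer2a, the receptor CD23 (ENSMUSG00000005540, chr8:3681737-3694175), was 0.279-fold (0.265 to 0.295) and Cr2, the complement receptor CD21 (ENSMUSG00000026616, chr1:195136811-195176716), 0.320-fold (0.305 to 0.337). Marcks, a protein kinase C substrate, was 0.370-fold and Zfp36l2, which speeds mRNA decay, 0.416-fold. Of the Slpi UMIs 92.2%, and of the Pclaf UMIs 52.6%, lay in 130 cells with at least 20 UMIs of Jchain, a gene of antibody-secreting cells, and without them the log2 ratio of Slpi with a pseudocount was 3.11 in place of 4.40. The proliferation list had a median of 2.63 (1.89 without those cells, 1.36 with cells thinned to 1000 UMIs), higher in 13 of 13 members, with Top2a, which untangles DNA, 12.3-fold and Stmn1, a microtubule regulator, 6.17-fold. The neutrophil granule list stood at 1.57 in the same B cells and S100a8, a neutrophil protein, at 586.5 CPM against 14.7 in naive, a sign of RNA from other cells. The immunoglobulin constant list had a median of 0.07 in B cells, plasma cell markers 0.34, platelet markers 0.16 and erythroid markers −0.21. Chosen after its values were seen, Ighg2c, the IgG2c heavy chain (ENSMUSG00000076612, chr12:113285325-113288932), stood at 0.892 CPM in naive B cells and 2581 at 14 days, while Igha, the IgA heavy chain, went from 2640.1 to 778 CPM. Few cells of the class carried these values, since Ighg2c at 14 days stood at 11758 CPM in the 130 Jchain-high cells and 64.4 in the other B cells, and naive Igha at 54248 CPM in 26 such cells and 51.8 in the others.

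CD8+ T cells at 14 days carried more killing and chemokine transcripts. Gzma (ENSMUSG00000023132, chr13:113093825-113100981) was 55.1-fold (47.6 to 64.1) and Gzmb (ENSMUSG00000015437, chr14:56258838-56262260) 66.3-fold (53.0 to 84.3), both proteases that kill target cells, and the chemokine Ccl4 was 20.8-fold (17.6 to 24.8). The cytotoxic list had a median of 2.11, with 10 of 11 members higher, and Ccl5 went from 1211 to 4990 CPM. Checkpoint receptors, which restrain T cells, had a median of 1.36 with 9 of 10 members higher, among them Lag3 at 14.6-fold and Pdcd1, which encodes PD-1, at 12.2-fold. Naive T cell genes had a median of −1.03, lower in 8 of 9 members, with the transcription factor Lef1 at 0.30-fold and the interleukin 7 receptor Il7r at 0.37-fold. Ccr9, a gut homing receptor (ENSMUSG00000029530, chr9:123678439-123784330), was 0.216-fold (0.187 to 0.249), Itgae, an integrin that binds epithelium, 0.183-fold, Pik3ip1, a brake on PI3 kinase, 0.224-fold and Rgcc, a cell cycle regulator, 0.227-fold. Ly6a, the antigen Sca-1, was 17.9-fold at 913 CPM, against 1502 in empty droplets. The proliferation list stood at 2.81 with Top2a 7.85-fold. All cells of the authors' proliferating T cell subtype in spleen (58, 307 and 289) lay in the CD8+ class, and without them the proliferation list in CD8+T cells, spleen at 14 days over naive spleen, was 3.08. They were left out of both libraries, 58 of 856 cells in naive and 307 of 998 at 14 days. This ratio therefore cannot say how much of the proliferation level that subtype held. Naive-like cells alone gave 0.06. The NK maturation list was at 2.02 in all CD8+ T cells and the myeloma growth factor list, with 3 of 8 members measured, at 0.09. The granule list was at 2.69 and the MHC class II list at 1.18 in these cells, signs of RNA from neutrophils and antigen-presenting cells.

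CD4+ T cells at 14 days had Lag3, an inhibitory receptor for MHC class II (ENSMUSG00000030124, chr6:124904361-124911705), 50.8-fold higher (31.1 to 89.4). The chemokine Cxcl10 was 47.9-fold (28.8 to 86.1), at 93.1 CPM against 149 in empty droplets, Ifi204, a DNA sensor, 233-fold from 2 naive UMIs (64.1 to 1931) and Ifit3, an antiviral protein (ENSMUSG00000074896, chr19:34583531-34588731), 15.01-fold (12.2 to 18.7). Lower genes were Ttc28 at 0.314-fold, Pdlim4 at 0.341-fold, Cd55, which shields cells from complement, at 0.358-fold and the sialyltransferase St8sia6 at 0.382-fold. The checkpoint list had a median of 1.35 with 9 of 10 members higher, Pdcd1 15.3-fold and Ctla4 5.92-fold. The regulatory T cell list had a median of 2.08 in CD4+ T cells, naive T cell genes −0.63 with 5 of 9 lower, and proliferation genes 0.42, in a class that held none of the proliferating T cell subtype.

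In NK cells at 14 days the all-gene median was −0.17. Proliferation genes had a median of 2.62, higher in 13 of 13, and Pclaf was 113-fold from 3 naive UMIs (38.6 to 551). The authors' proliferating NK subtype was 1 of 165 NK subtype cells in naive spleen and 42 of 170 at 14 days. The histone genes Hist1h1b, at 18.9-fold, and Hist1h3c, at 124-fold from 1 UMI (22.02 to 4921), were higher, as was the interferon-induced Ifi44 at 44.1-fold (17.0 to 163). The potassium channel Kcnj8 was 0.167-fold, Gprin3 0.1701-fold, Hs3st3b1, a heparan sulfate enzyme, 0.252-fold and the B cell gene Fcer2a 0.304-fold. NK maturation genes had a median of −0.27, near the all-gene median, with the transcription factor Zeb2 at 0.46-fold. The cytotoxic list was at 0.22 with Gzma 1.29-fold. MHC class II genes, a sign of other cells here, stood at −0.54 in NK cells.

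**Figure D3:**
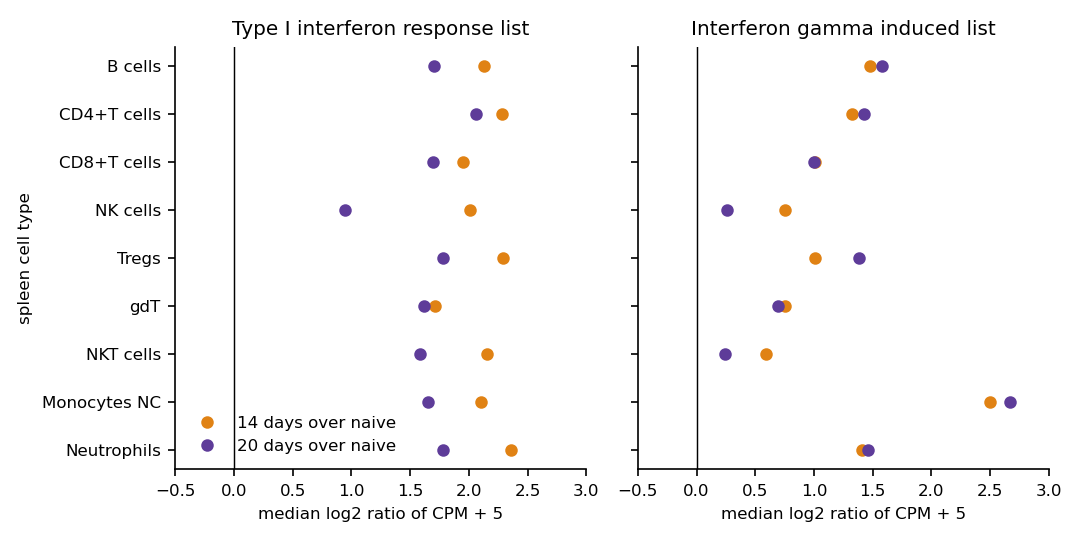
Points show the median log2 ratio (CPM + 5) of the type I interferon and interferon gamma lists in 9 spleen cell types, at 14 and at 20 days over naive. In B cells the type I interferon median is 2.13 at 14 days and 1.70 at 20 days, and in NK cells 2.01 and 0.95.

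Neutrophils and non-classical monocytes of the spleen, with under 100 cells in a library and added after the data were examined, shared the interferon pattern at 14 days. The type I interferon median was 2.36 in neutrophils, above an all-gene median of −0.31, and 2.11 in non-classical monocytes, above −0.15. In neutrophils Ifit2, which blocks viral translation, was at least 16.4-fold and Cxcl10 at least 7.2-fold (0 naive UMIs, floor of 3 counts). The level of Cxcl10 there lay below its 149 CPM in empty droplets of that library. Immediate early genes, which respond to stimuli and to cell handling, had a median of −1.75 in neutrophils with 8 of 9 lower, and Ptgs2, the prostaglandin enzyme COX-2, was 0.128-fold and the chemokine Cxcl2 0.173-fold. The suppressor list was at −0.88 with Il1b at 0.42-fold, the mature neutrophil list at −0.26 and the granule list at 0.43 with lactoferrin (Ltf) 1.62-fold. By the authors' neutrophil subtypes Neu1 to Neu4, Neu4 was 41 of 46 cells in naive spleen and 133 of 208 at 14 days. The makeup of the class thus differed, and its effect on these lists was not tested. The myeloma growth factor list stood at −0.41 in neutrophils. Scaling by the median ratio of genes, a shift of 0.46 for the median gene there, turned this sign and that of the mature list. Non-classical monocytes had Iigp1 111-fold higher at the floor of 3 counts for 0 naive UMIs, with an interval from 90.2. Cxcl9, a chemokine for T cells, was 246-fold from 2 UMIs (68.0 to 2035), and Cxcl10 146-fold. By the authors' subtypes this class differed in makeup between libraries, with 39 non-classical, 35 classical and 10 interferon-marked cells in naive spleen and 0, 2 and 111 at 14 days. Its fatty acid transporter Cd36 was 0.0141-fold from 2 UMIs against 61 (0.00166 to 0.0530) and the lipid carrier Apoe 0.0672-fold. The immediate early medians in B, CD4+ T, CD8+ T and NK cells were −0.41, −0.13, −0.34 and −0.52.

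Spleen at 20 days was compared with naive spleen to describe late myeloma. CD8+ T cells had Gzma at 89.5-fold (77.3 to 104) and Gzmb at 61.4-fold (49.0 to 78.0), with Ccl4 at 33.2-fold (28.1 to 39.5) and its relative Ccl3 at 38.6-fold. The cytotoxic list had a median of 3.4, with 10 of 11 members higher, and in naive-like CD8+ T cells alone it was 0.60. Ccl5 stood at 12803 CPM, 10.6-fold naive, and the granule protein gene Nkg7 was 2.98-fold. The checkpoint list was at 1.20 with Pdcd1 13.3-fold, Lag3 15.2-fold and Tox, a factor of chronically stimulated T cells, 1.93-fold. Naive T cell genes had a median of −1.01 with 8 of 9 lower, Ccr9 was 0.167-fold (0.142 to 0.196), Ramp1, a neuropeptide receptor partner, 0.203-fold, Rflnb, a filamin partner, 0.233-fold and Pik3ip1 0.230-fold. The NK maturation list stood at 3.15 and proliferation genes at 2.58 in these cells.

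B cells at 20 days had Slpi 50.9-fold higher (45.6 to 57.0), Iigp1 194-fold (113 to 365), Ly6c2 18.7-fold and Pclaf 16.1-fold, with 97.7% of Slpi UMIs and 46.5% of Pclaf UMIs in 45 Jchain-high cells. Without those cells the log2 ratio of Slpi was 2.27 in place of 5.39. The Slpi interval counts each UMI as independent, so it is too narrow for UMIs held by so few cells. Lower were the complement protein gene Cfp at 0.224-fold, the lipid receptor Cd36 at 0.240-fold, Marcks at 0.256-fold and Cr2 at 0.352-fold (0.331 to 0.374). The type I interferon list had a median of 1.70 with 17 of 17 higher, the interferon gamma list 1.58, MHC class I 0.85 and proliferation 1.71 with 12 of 13 higher (1.46 without Jchain-high cells, 0.92 with cells thinned to 1000 UMIs). MHC class II genes had a median of −0.04 (percentile 37.9), near the all-gene median of −0.07. The immunoglobulin constant list was at −0.08. Scaling by the median ratio of genes, a shift of 0.09 for the median gene, turned the sign of this list and of the MHC class II list. Plasma cell markers were at −0.31, with Ighg2c at 3525 CPM, Ighg2b at 3851 CPM against 639.7 in naive, and Igha at 66.3 CPM. Ighg2c stood at 32361 CPM in the 45 Jchain-high cells and 40.8 in the other B cells. Ighg2b stood at 30869 CPM in the Jchain-high cells and 586 in the other B cells. Its level in empty droplets of that library was 532 CPM, and in the other B cells of naive spleen 26.7 CPM. The granule list was 1.62 in B cells, again a sign of other cells, and S100a8 stood at 179.9 CPM.

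CD4+ T cells at 20 days had Ccl4 (ENSMUSG00000018930, chr11:83662584-83664683) 184.7-fold higher (89.3 to 460.5), at 167 CPM against 250 in empty droplets. Lag3 was 34.5-fold (21.0 to 60.8), Ifit3 13.1-fold and Tnfrsf4, the costimulatory receptor OX40, 10.6-fold (8.71 to 12.95). Cdk5rap1 was 0.264-fold, St8sia6 0.322-fold, Pdlim4 0.349-fold and Jun, an immediate early gene, 0.394-fold. Type I interferon genes had a median of 2.06 with 16 of 17 higher, checkpoint genes 1.23 with Pdcd1 14.8-fold, the regulatory T cell list 1.72 and naive T cell genes −0.61 with Il7r at 0.49-fold.

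NK cells at 20 days had proliferation genes at 2.60, with Hist1h3c 268-fold from 1 naive UMI (47.8 to 10633), Pclaf 111-fold from 3 (37.5 to 539), Hist1h1b 32.95-fold and Spc24, a kinetochore gene, 107-fold from 1 (18.8 to 4268). The proliferating NK subtype was 25 of 183 NK subtype cells, against 1 of 165 in naive spleen. The B cell genes Cr2, at 0.0490-fold (0.0176 to 0.110), and Fcer2a, at 0.113-fold, were lower, as were the widely expressed tetraspanin Cd81 at 0.231-fold and the actin linker Actn1 at 0.177-fold. MHC class II genes were lower in 9 of 9, with a median of −1.15 against an all-gene median of −0.14, a sign of fewer B cell transcripts in NK cells. The NK maturation list was at 0.44 with Klrg1, a receptor of mature NK cells, 2.33-fold and the perforin gene Prf1 1.35-fold. The cytotoxic list had a median of 0.54 with Ccl5 2.04-fold and Gzma 1.74-fold, and the type I interferon list 0.95 with 13 of 17 higher.

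**Figure D4:**
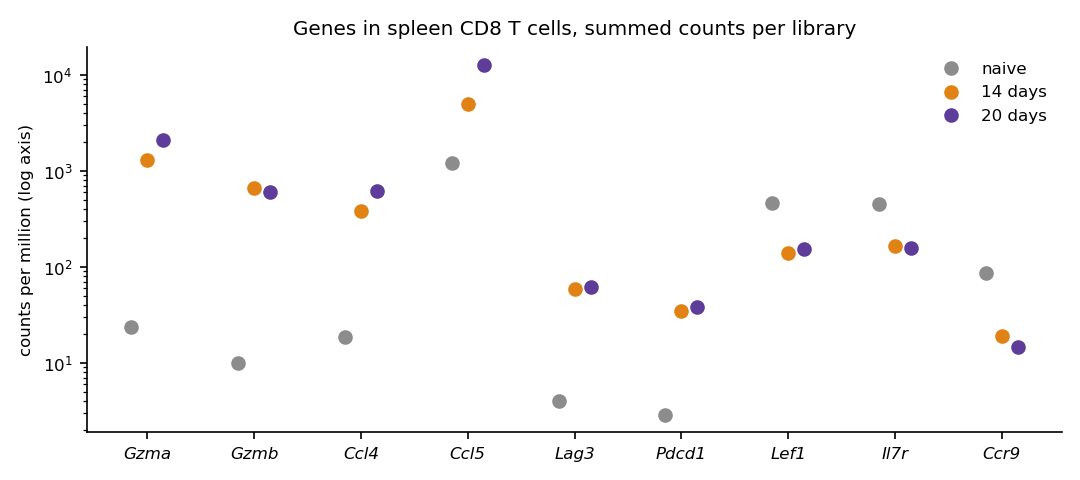
Points show CPM on a log axis of effector, checkpoint and naive T cell genes in spleen CD8+ T cells of naive, 14-day and 20-day mice, 1 library each. Ccl5 stands at 1211, 4990 and 12803 CPM.

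At 20 days spleen neutrophils had a type I interferon median of 1.78 and an immediate early median of −2.61, with Egr1, an early response factor, at 0.0410-fold, Ptgs2 at 0.0505-fold and Cxcl2 at 0.0772-fold. Their suppressor list was at −1.51 with 11 of 12 lower, mature neutrophil genes at −0.91, granule genes at 0.95 with Ltf 2.37-fold, and the all-gene median at −0.25. Subtype makeup differed here too, with Neu4 at 53 of 105 cells against 41 of 46 in naive spleen, and its effect was not tested. The non-classical monocyte class, with 50 of its 51 cells in the interferon subtype, had an interferon gamma median of 2.67, an MHC class II median of 0.50 and a suppressor median of −1.43, with Apoe at 0.0449-fold and the enzyme Ace at 0.0441-fold.

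The step from 14 to 20 days asked which genes differed within myeloma. In CD8+ T cells Ifng, the interferon gamma gene, was 3.597-fold (3.36 to 3.86), Cx3cr1, a receptor of effector cells, 2.80-fold (2.55 to 3.09), Klrg1 2.70-fold (2.38 to 3.07) and Ccl5 2.57-fold (2.54 to 2.59), and the cytotoxic list had a median of 0.68 with 8 members higher. The type I interferon list had a median of −0.58 in B cells, −0.22 in CD4+ T cells, −0.28 in CD8+ T cells and −1.02 in NK cells, where 14 members were lower. Proliferation genes in B cells had a median of −0.93 with 10 of 13 lower, Mki67, a marker of cycling cells, at 0.330-fold and Cenpf, a kinetochore gene, at 0.286-fold. The B class held 130 Jchain-high cells at 14 days and 45 at 20 days. Without them the proliferation medians over naive at 14 and 20 days lay closer together, so part of this fall may rest on them. NK cells had Cx3cr1 at 2.70-fold, Cma1, a protease, at 2.25-fold and an NK maturation median of 0.70, while Cxcl10 was 0.140-fold, Slfn5, an interferon-induced gene, 0.227-fold and Marcksl1 0.114-fold. CD4+ T cells had Mid1, a ubiquitin ligase, at 2.88-fold, Ccl4 at 2.22-fold and Cxcl10 at 0.307-fold, and B cells had Mid1 at 2.68-fold.

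Naive BM was compared with naive spleen to describe the tissues before myeloma. BM held 46.8-fold the neutrophil share (35.3 to 63.4) and 86.2-fold the GMP/GP share (39.2 to 236.7), and 0.527-fold the B cell share (0.487 to 0.571), 0.0317-fold the CD4+ T cell share and 0.0709-fold the CD8+ T cell share. BM B cells expressed Rag1, the enzyme that cuts antigen receptor genes (ENSMUSG00000061311, chr2:101638282-101649501), with 972 UMIs against 3 in spleen B cells, 1177-fold (401 to 5715). The transcription factors Myb and Sox4, both of lymphoid precursors, were 27.6-fold (23.1 to 33.3) and 25.03-fold (21.5 to 29.3), and the sodium pump subunit Atp1b1 31.3-fold (27.4 to 36.0). Cr2 was 0.117-fold (0.0984 to 0.138), the survival gene Bcl2a1b 0.184-fold, Pxdc1 0.258-fold and Ly6a 0.262-fold. MHC class II genes were lower in 9 of 9 with a median of −1.29 against an all-gene median of 0.12, with Cd74 at 0.45-fold and H2-Aa at 0.36-fold. Proliferation genes were higher in 9 of 13 with a median of 1.34 and Top2a at 4.38-fold, and this median was 0.34 without cells of doublet score above 0.5. The granule list was higher in 10 of 10 in BM B cells with a median of 3.53 and the mature neutrophil list at 2.35, signs of neutrophil RNA. In neutrophils, added after the data were examined, Il1b was 0.102-fold in BM, immediate early genes had a median of −1.98 and suppressor genes −1.29, with erythroid markers at 3.68. The neutrophil subtypes differed in makeup between the tissues, with Neu4 at 46.8% in naive BM and 89.1% in naive spleen.

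Empty droplets, barcodes of 1 to 50 UMIs, were compared to ask which RNA floated free in the spleen suspensions. Relative to naive spleen Ighg2b (ENSMUSG00000076613, chr12:113302965-113307933) was 4.07-fold at 14 days (3.6 to 4.62) and 4.36-fold at 20 days (3.82 to 4.98), and Ighg2c 19.0-fold (16.0 to 22.8) and 11.4-fold (9.48 to 13.75). Igha was 0.395-fold and 0.119-fold, and Ighm, the IgM heavy chain, 0.801-fold and 0.444-fold. Isg15 was 2.89-fold and 2.74-fold. S100a8 was 2.11-fold and 1.71-fold. These folds depended on the range of barcodes, as for Ighg2b in empty droplets, spleen at 14 days over naive spleen, and for Ighg2c in empty droplets, spleen at 20 days over naive spleen. At 14 and 20 days Ighg2c was 67.8-fold and 39.0-fold in barcodes of 1 to 10 UMIs and 6.36-fold and 3.83-fold in those of 10 to 100. In barcodes of 1 to 10 UMIs Ighg2b was 5.94-fold and 6.55-fold and Isg15 4.39-fold and 3.78-fold. In barcodes of 10 to 100 UMIs Ighg2b was 2.34-fold and 1.76-fold, Isg15 1.32-fold and 1.10-fold, and S100a8 turned to 0.618-fold and 0.672-fold.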

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

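The tests of free RNA for the interferon pattern and those on antibody genes were chosen after the result was seen.

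Lymphoid progenitors at 14 days had 2.84-fold their naive share in spleen and 0.284-fold in BM, and neutrophils at 20 days had 2.15-fold in spleen and 0.768-fold in BM. These opposite directions in the tissues were not tested, since each group had 1 library. The authors' broad names put 28 of 29 naive and 83 of 83 of these spleen lymphoid progenitors at 14 days among B cells. In empty droplets of the spleen Ighg2b was 4.07-fold naive at 14 days and 4.36-fold at 20 days, Ighg2c 19.0-fold and 11.4-fold, and Ighg3, the IgG3 heavy chain, 2.56-fold at 14 days. The range of barcodes mattered for Ighg2c in empty droplets, spleen at 20 days over naive spleen, and for the other pairs. With 10 to 100 UMIs Ighg2b was 2.34-fold and 1.76-fold and Ighg2c 6.36-fold and 3.83-fold at 14 and 20 days.

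The type I interferon list was higher than in naive spleen in each of the 9 cell types examined at both days. Free RNA at the highest share that markers of absent cell types allowed gave at most 23.4% of the rise in B, CD4+ T and CD8+ T cells, and naive-like T cells alone kept at least 66.9% of the list median, which argues against free RNA in those 3 types, and against subtype makeup in CD4+ and CD8+ T cells, as the whole cause. For NK cells a first bound from B cell markers gave up to 112% and was then replaced, since naive NK cells held those markers far above CD4+ T cells, by the share found in CD4+ T cells, which gave at most 16.8%, so free RNA stays open there, and in the other 5 types it was not tested, nor was subtype makeup outside CD4+ and CD8+ T cells, where the non-classical monocyte class went from 10 interferon-marked cells of 84 to 111 of 113 at 14 days. A difference in handling between libraries cannot be told apart from myeloma with 1 library per group. A response to myeloma may underlie the pattern, but it is an untested hypothesis here.

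Of 14 B cell marker and MHC class II genes, 7 were at least 1.5-fold lower in spleen NK cells at 14 days than in naive NK cells (median log2 ratio −0.59, all-gene median −0.17) and 14 at 20 days (median −1.25). Free RNA of the naive library would reach all cell types alike, but naive NK cells held 14.3-fold the B cell marker level of naive CD4+ T cells (interval 13.1 to 15.5), which argues against it. Doublets of B and NK cells in the naive library stay open, since without cells of doublet score above 0.5 the median kept 154% of its size at 14 days and 51.0% at 20 days. The summed B cell marker level also fell in B cells themselves, from 7067 CPM in naive spleen to 4565 at 14 days and 5249 at 20 days. In NK cells it went from 1327 to 863 and 475 CPM. A lower level of these markers in B cells thus stays open as a source of the 14-day fall. No biological explanation was tested.

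Cells of the B class with at least 20 UMIs of Jchain, a gene of antibody-secreting cells, numbered 26 in naive spleen, 130 at 14 days and 45 at 20 days, though the gate removed CS1+ and 3H2+ cells. As background, the 5T33 clone makes IgG2b, and Ighg2b led 21.5% of these cells at 14 days and 51.1% at 20 days (upper bounds 29.6% and 66.3%), which argues against that clone as the whole source. Ighg2c stood at least 11.9-fold above empty droplets in these cells, which argues against free RNA. Cells of the clone as a part of them stay open, as does a host antibody response, which was not tested. These tests cover Jchain-high cells only. In the other B class cells Ighg2b stood at 26.7 CPM in naive spleen, 296 at 14 days and 586 at 20 days. Empty droplets of the same libraries held 122, 497 and 532 CPM of Ighg2b, and the source of this rise was not tested.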

How the results depend on the processing

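Tests chosen after the result was seen were broad cell names, doublet scores above 0.5 and the 5% highest Scrublet scores left out, naive-like T cells alone, B class cells with at least 20 Jchain UMIs left out, and the proliferating T cell subtype left out of CD8+ T cells; the gene lists recomputed were picked after all list medians were known. Of the recomputed values, 102 shares, 272 list medians and 592 single genes lay within the counting interval, 22 shares, 133 list medians, 334 genes and 14 empty-droplet values moved beyond it, and 2 shares, 2 list medians and 2 empty-droplet values reversed, a label that needs a reported interval without the value of no change. Some settings could change little. Leaving out Scrublet calls kept 14 shares, 36 list medians and 90 genes within the interval and moved 1 list median and 7 genes. Taking immunoglobulin and haemoglobin genes out of the total kept 37 list medians and 97 genes and moved none. Thinning moved 27 list medians and kept 9, and a pseudocount of 20 CPM moved 27 and kept 10. The totals are thus no measure of stability. No paired analysis was run, and each group had 1 library. Cells with at least 1000 UMIs were not run in BM, where 2 of 3 matrices were not used here. Rare types such as macrophages rest on few cells (43, 4 and 14), which limits their folds. The cause was not tested for any value below unless stated; list values are median log2 ratios, over naive spleen unless stated.

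With the 5% highest Scrublet scores out, the cytotoxic list in CD8+ T cells (20 over 14 days) was 0.75, proliferation in BM over spleen B cells 0.78, the NK share at 20 days 1.11-fold (0.882 as reported, so on the other side of 1, though that interval included 1), and the type I interferon list in NK cells 1.44 at 14 days and 0.69 at 20 days. With doublet scores above 0.5 out, the same cytotoxic list was 0.85, BM proliferation 0.34, interferon in CD8+ T cells 2.32 and 1.82 at 14 and 20 days and in NK cells 1.41 at 14 days. BM share folds at 14 and 20 days were then 0.188 and 0.0723 for B cells, 3.48 and 2.17 for GMP/GP, 2.98 and 6.60 for myeloid progenitors and 1.23 and 0.858 for neutrophils, and 0.234 for non-classical monocytes at 14 days.

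With B cells out of the denominator, spleen folds at 20 days were 0.773 for CD4+ and 1.44 for CD8+ T cells. In BM they were 2.15 and 1.26 for GMP/GP, 1.52 and 3.38 for myeloid progenitors, 0.154 for non-classical monocytes at 14 days, and 0.882 (reversed) and 0.602 for neutrophils, where the smaller denominator accounts for the shift. Broad cell names gave 0.130 for BM B cells and 1.23 for spleen NKT cells at 20 days, and 0.918 (reversed) and 1.60 for BM monocytes at 14 and 20 days, where the broad name also takes in non-classical monocytes and most myeloid progenitors. Cells with at least 1000 UMIs gave 0.118 for spleen macrophages at 20 days.

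Without Jchain-high cells interferon in B cells was 2.30 and 1.77. Without the proliferating T cell subtype, interferon in CD8+ T cells was 2.25 and 2.01. With 5% of empty-droplet RNA subtracted, interferon in B cells at 14 days was 2.32. Thinned to 1000 UMIs, which weights each cell equally, the cytotoxic list was 4.09 at 20 days and 0.92 over 14 days, BM proliferation 1.07, interferon in B cells 2.51, 1.90 and −0.47 (14, 20, and 20 over 14 days), in CD8+ T cells 2.47 and 2.02, and in NK cells 1.12 at 20 days. Naive-like cells alone gave a cytotoxic value of 0.60 at 20 days, interferon in CD4+ T cells of 1.52 and 1.78, and in CD8+ T cells of 1.93 at 20 days.

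A pseudocount of 1 gave 4.65 for the cytotoxic effector list in CD8+T cells, spleen at 20 days over naive spleen, 1.93 for BM proliferation, and interferon of 2.54 and 1.90 in B cells, 2.11 in CD4+ T cells at 20 days, and 2.41 and 1.89 in CD8+ T cells. A pseudocount of 20 gave 3.13 and 0.62 (over 14 days) for the cytotoxic list, 0.66 for BM proliferation, and interferon of 1.66, 1.29 and −0.49 (20 over 14 days) in B cells, 1.75 and 1.70 in CD4+, 1.56 and 1.37 in CD8+ T cells, and 1.41 and 0.73 in NK cells; a larger pseudocount shrinks ratios by construction. Scaling by the median ratio gave 3.34 for the cytotoxic list at 20 days, 1.21 for BM proliferation and 1.81 for interferon in B cells at 20 days. It reversed the neutrophil (mature) list in Neutrophils, spleen at 14 days over naive spleen, to 0.28, and the immunoglobulin constant list in B cells, spleen at 20 days over naive spleen, to 0.048. It also turned the sign of the myeloma growth factors list in Neutrophils, spleen at 14 days over naive spleen, to 0.09, and of the MHC class II list in B cells, spleen at 20 days over naive spleen, to 0.07, where the reported intervals included 0.

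Values were recomputed for Ighg2b in empty droplets, spleen at 14 days over naive spleen, for Ighg2c in empty droplets, spleen at 20 days over naive spleen, and for the other pairs. In barcodes of 1 to 10 UMIs, folds at 14 and 20 days were 5.94 and 6.55 for Ighg2b, 67.8 and 39.0 for Ighg2c, 4.39 and 3.78 for Isg15, and 2.70 and 1.94 for S100a8. In barcodes of 10 to 100 UMIs they were 2.34 and 1.76, 6.36 and 3.83, 1.32 and 1.10, and 0.618 and 0.672 (both reversed).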

Other observations

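The NKT cell values, S100a8, Slamf7 and the subtype values were chosen after the data were seen, the other genes were named by a rule fixed before, and no tests were run. In spleen, regulatory T cells (Tregs), which restrain immune responses, had a type I interferon median of 2.29 at 14 days and 1.78 at 20 days. Their regulatory T cell list was at 0.90 and 0.96, with Tnfrsf4 2.86-fold and 2.38-fold, and Gzmb was 40.5-fold and 23.2-fold. Their share of spleen cells was 3.07%, 3.05% and 2.65%. Gamma delta T cells, which respond without classical antigen presentation, had interferon medians of 1.71 and 1.62, with Isg15 8.37-fold and 7.89-fold, and Dapl1 at 0.229-fold and 0.244-fold. Isg15 stood at 442 and 420 CPM in empty droplets, and free RNA was not tested in this class. NKT cells at 20 days had Gzma at 33.3-fold (26.8 to 42.0), Gzmb at 38.8-fold and a cytotoxic median of 2.60, while at 14 days the same class held S100a8 at 17189 CPM against 52.5 in naive, a sign of neutrophil RNA.

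BM neutrophils fell into 4 subtypes named by the authors. Neu4 was 46.8% of them in naive BM, 34.7% at 14 days and 17.9% at 20 days, while Neu3 was 22.7%, 38.7% and 42.6% and Neu2 29.3%, 24.5% and 37.0%. Spleen neutrophils were 89.1%, 63.9% and 50.5% Neu4. Proliferating NK cells were 1, 42 and 25 cells in the 3 spleen libraries, and Slamf7, which encodes the CS1 protein of the gate, stood at 111, 162 and 196 CPM in NK cells.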
